A study of Homo sapiens with 35 samples.

How the data were processed

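RNA was sequenced from H1 cells, an established human embryonic stem cell line, in 32 bulk samples (16 groups of 2) and 3 single-cell samples, 35 in all. Per the labels, bulk libraries were stranded total RNA read single-end at 85 bases, and single cells were prepared with droplet 3' chemistry after sorting, aiming at 1000 to 5000 cells. Groups were taken from the labels by treatment and time. The pair of untreated samples at 24 h has no column in the deposited table and could not be used, and 0 columns were left unassigned. The labels do not say whether replicates were separate inductions or repeated libraries, so the spread between them may be technical. By their labels replicates share a number across groups and nothing else, and they were not treated as pairs.

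The authors deposited the bulk data in the form of expected counts per gene, with fractional values, for 16103 genes in 30 libraries; their notes list Salmon 1.4.0, limma 3.48.1 and edgeR 3.34.0 without saying what each did. The deposited single-cell matrices hold UMI counts per gene and cell, made per the file headers with Cell Ranger 3.0.2 on GRCh38, and Seurat 4.0.2 is listed in the notes. A deposited matrix that aggregates the same cells at lower counts was left out. Bulk libraries held 4.57 to 49.5 M (mega) counts, and single-cell libraries 83.2, 35.4 and 45.8 M UMIs.

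Expected counts were rounded to whole counts. Genes were tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F-test, two-sided), in 1 fit per time point over all its libraries, and in 1 fit over 6 h and 24 h for the tests of whether an effect differed between times. Calls were made at a Benjamini-Hochberg false discovery rate of 0.05 over the genes tested in each of 24 comparisons. The fits had 6, 5 and 4 residual degrees of freedom at 6 h, 24 h and 72 h. A standard error was the log2 change divided by the root of the F statistic, and 95% intervals of differences rest on it. Levels are counts per M counts (CPM) with TMM scaling, given as mean and SD over libraries. A fold against a group with 0 counts was bounded with a floor of 3 counts over the group and written as at least that fold.

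Lists of genes were fixed before the data were examined, 26 in all, covering cell types, signalling targets, cell cycle, metabolism and stress. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Signatures of 100 genes were made from the single-cell libraries by their CPM ratio (at least 50 CPM in the higher library), and tested the same way; since they come from the same study they are not independent evidence. Overlap between comparisons that share controls was set against 20 simulated draws in which no group changed.

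The groups, comparisons, lists, alternatives and the rule for naming genes were chosen before the data were examined. Named were, per main comparison, the 8 largest rises and the 8 largest falls among called genes with at least 5 CPM in the higher group and every library of 1 group above every library of the other, without clone identifiers (4 and 4 in other comparisons). Up to 4 members with the smallest p from each fixed list with called members, and 12 stage genes, were added. In single cells the 10 genes with the largest CPM ratio in each direction with at least 50 CPM in the higher library were named, with fixed markers.

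Tested on simulated data with 200 changed genes, the fits recovered 82% of 2-fold and 100% of 4-fold changes at 6 h, 61% and 88% at 24 h, and 71% and 92% at 72 h. The false share of the calls was 7.61%, 12.9% and 6.86% in these single draws, above the nominal 5%.

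Single-cell data were handled in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Doublets were called with Scrublet, which marked 0, 0 and 6 cells, so almost none were removed. Whether doublets were missed was not tested. Each library was clustered alone (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5 with leidenalg 0.10.2 and igraph 0.11.9, seed 0). A cluster was named for the cell type, of 10, with the largest share of its fixed markers each present in at least 10% of cells, with at least 3 such markers. It stayed unnamed if its median UMI count lay under 33.3% of the median of its library and none of the type's markers was among its 10 leading genes, or if another type had more markers among these (at least 2 in the rule tried first). After the clusters were seen, a lead of 15% over the next type was added to this rule, so 2 naming rules were tried; the lead took the name from 67.1%, 11.9% and 69.7% of the cells at 36 h, in Endo and in Meso. Shares of cells with a UMI were counted after thinning every cell to 2000 UMIs, and cells with fewer were left out. Their intervals are exact (Clopper-Pearson) and those of CPM are exact Poisson, at 95%; all cover counting error only. With 1 library per condition no test between conditions was made. Of 33539 features 48 duplicated symbols were left out.

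The alternatives were DESeq2 size factors (RLE), no filter on low counts, a stricter filter (at least 5 CPM in 2 libraries), a replicate block, limma-voom, 1 fit over all libraries, DESeq2 1.42.0, leaving out each library in turn, signatures of 50 genes, and for cells no filter, doublets kept, 1000 variable genes, 15 components and Leiden resolutions of 0.3 and 1.0. In a fit without 1 replicate the lone sample of a group was assumed to vary like the other groups. Added after the data were seen were fits without the BRD-alone libraries or without the MTRNR2L genes and 6 genes with high counts, clusters named after thinning, leaving out the top 5% of doublet scores, the naming rule tried first, and overlaps with 1 Activin A library for each comparison. Figures were drawn with matplotlib 3.10.9.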

Results

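Definitive endoderm, the germ layer that forms gut, liver and pancreas, was induced from H1 human embryonic stem cells, and gene expression was measured by RNA-seq in bulk and in single cells. The labels list 32 bulk samples in 16 groups of 2 and 3 single-cell samples of 1 library each. The pair of untreated samples at 24 h has no column in the deposited table, so 30 bulk libraries in 15 groups of 2 were compared, and every bulk value below rests on n = 2 libraries per group. Activin A (AA), a TGF-beta family ligand used in place of Nodal, was given at 100 ng/ml, with CHIR99021 (CHIR), a GSK3 inhibitor that turns on Wnt signalling, at 3 µM on day 1. Other arms list compounds by the code names BRD and JNJ where Activin A would stand, or BRD with an addition named LoAA. Cells were collected unsorted at 6 h and 24 h and as sorted definitive endoderm at 72 h. The comparisons ask how CHIR alone, Activin A and each compound change the cells at 6 h and 24 h, and how endoderm made with the compounds differs from endoderm made with Activin A.

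Bulk libraries held 4.57 to 49.5 M (mega) counts. Those of 6 h held 10.8 to 17.2 M and those of 24 h 13.0 to 29.6 M, apart from BRD alone, with 9.65 and 11.8 M at 6 h and 6.75 and 49.5 M at 24 h. The 72 h libraries held 4.57 to 7.59 M. The titles number the libraries in series 33 (6 h), 38 (24 h) and 46 (72 h and BRD alone). MTRNR2L12, a nuclear copy of mitochondrial ribosomal RNA, took 6.18% to 10.8% of the counts in the libraries of series 46, while the 10 MTRNR2L genes together took at most 1.10% elsewhere. In the groups of series 38, 112 to 298 genes had 0 counts in 1 replicate and at least 50 in the other, against 10 to 20 genes at 6 h and 9 to 16 at 72 h. The spread between replicates was wider at 24 h, with a common biological coefficient of variation of 0.406 against 0.140 at 6 h and 0.165 at 72 h.

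The stage genes followed throughout are placed on GRCh38 by GENCODE release 29, which lists each as protein coding. SOX17 lies on chromosome 8 (54457935 to 54460888), FOXA2 on chromosome 20 (22581005 to 22585455), CXCR4 on chromosome 2 (136114349 to 136118165) and EOMES on chromosome 3 (27715949 to 27722711). TBXT lies on chromosome 6 (166157656 to 166168700), MIXL1 on chromosome 1 (226223618 to 226227054), GSC on chromosome 14 (94768216 to 94770230) and LEFTY1 on chromosome 1 (225886282 to 225911382). NODAL lies on chromosome 10 (70432315 to 70447951), POU5F1 on chromosome 6 (31164337 to 31180731), SOX2 on chromosome 3 (181711924 to 181714436) and AXIN2 on chromosome 17 (65528563 to 65561647).

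**Figure D1:**
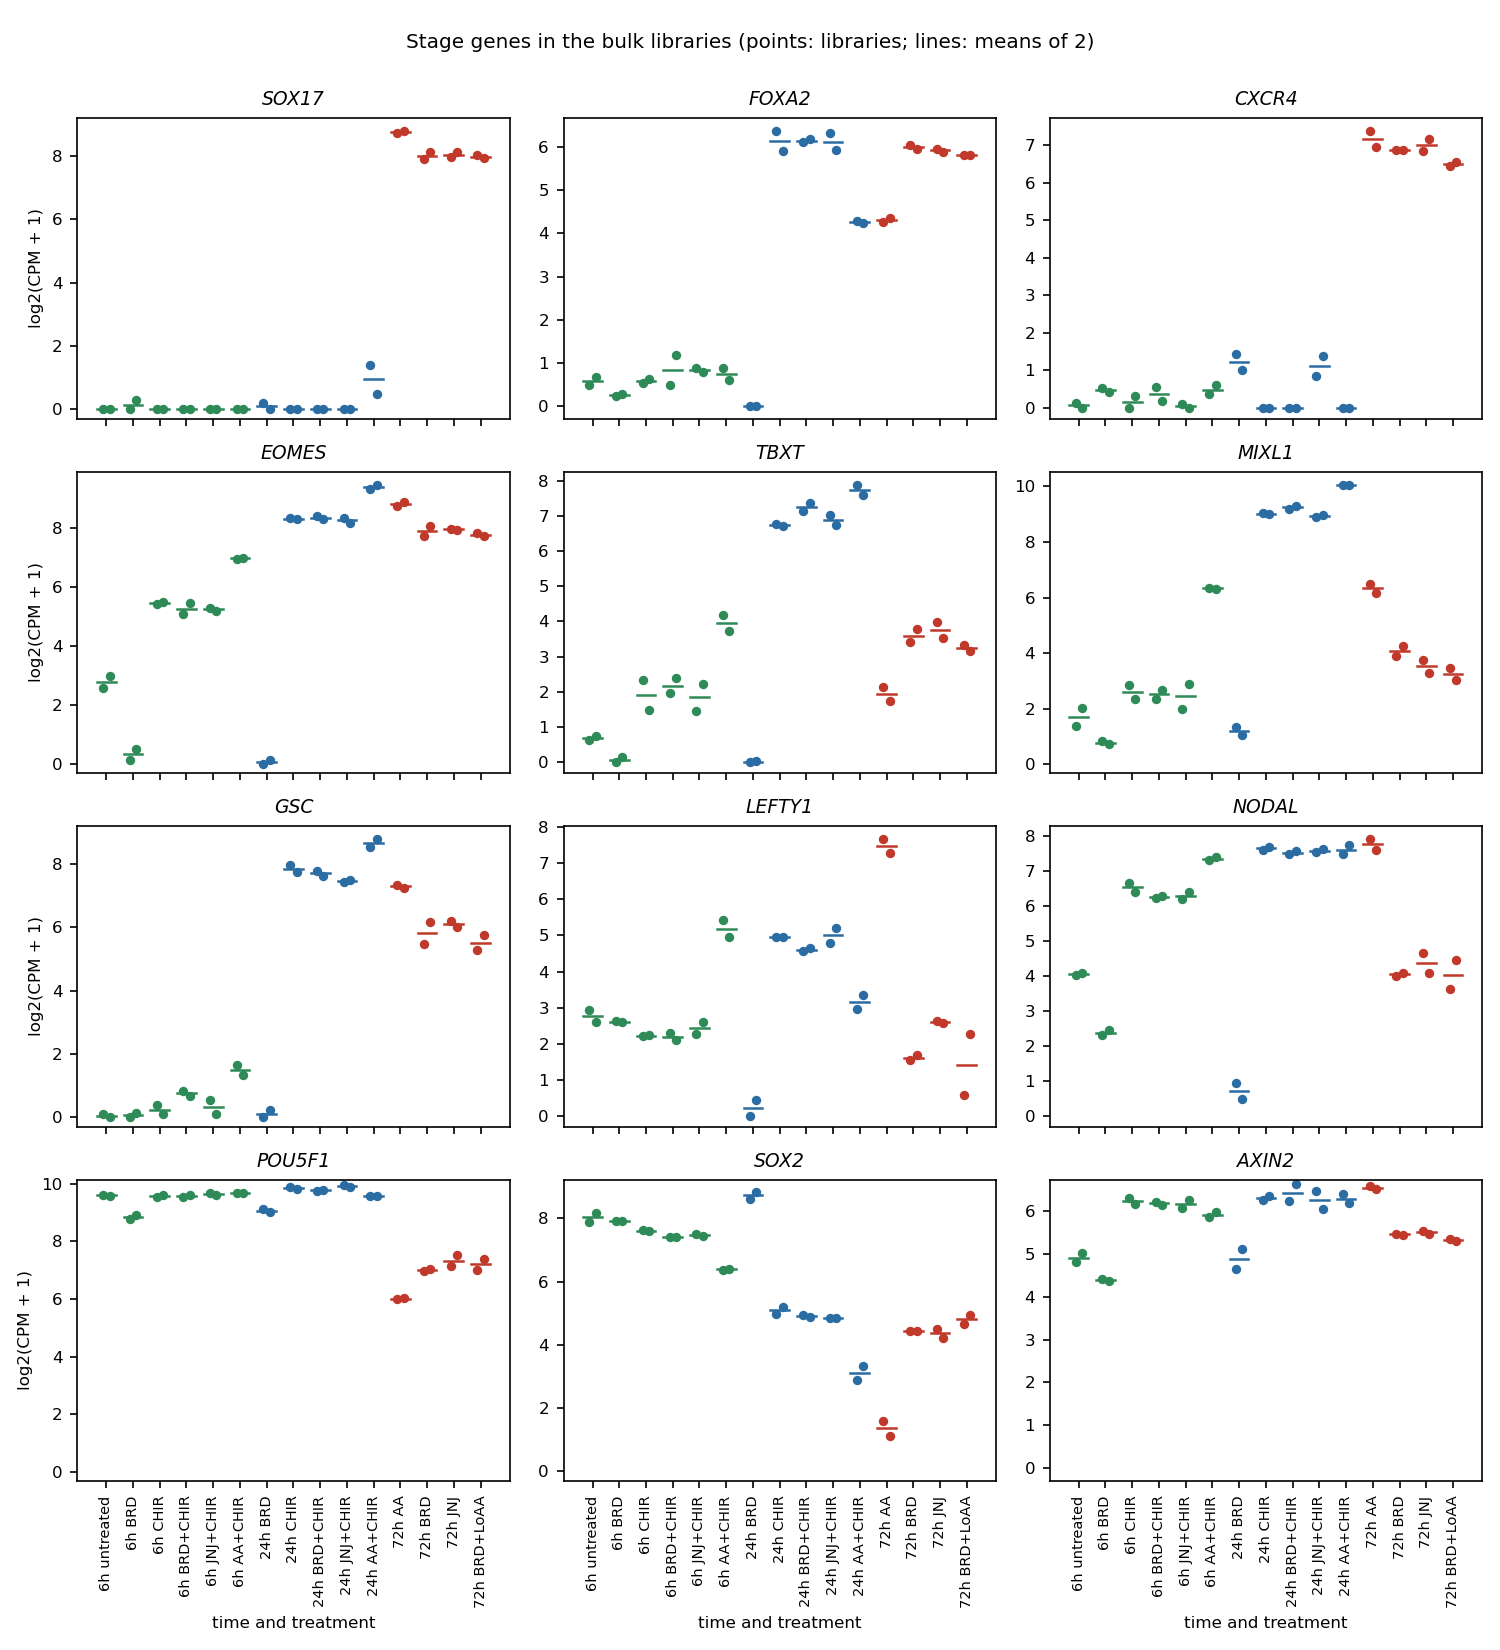
Level of each of the 12 stage genes, as log2 of CPM (counts per M counts of the library) plus 1, in the 15 bulk groups; points are libraries, lines are means of 2, and colours mark 6 h (green), 24 h (blue) and 72 h (red). EOMES stood at 43.3 CPM with CHIR at 6 h, 320.2 at 24 h and 452 in cells sorted after Activin A.

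CHIR alone at 6 h switched on Wnt targets and the first primitive streak genes, the genes of the embryonic structure from which endoderm and mesoderm arise. SP5, a transcription factor that Wnt signalling induces directly, rose from 5.50 ± 2.20 (SD, n = 2) to 71.4 ± 0.897 CPM (counts per M counts), a log2 change of 3.71 ± 0.20 (SE). EOMES, the T-box factor that endoderm specification needs, rose from 5.97 ± 1.41 to 43.3 ± 1.92 CPM (log2 change 2.86 ± 0.19). NODAL, the ligand of the pathway that Activin A mimics, rose from 15.7 ± 0.489 to 92.0 ± 11.6 CPM (2.56 ± 0.12), and FST, which binds and blocks Activin, rose by 3.10 ± 0.12 on the log2 scale. POU5F1, a core pluripotency factor, stayed at 763 against 771 CPM (adjusted p = 0.96), while its partner SOX2 fell from 262 to 195 CPM, a log2 change of -0.43 ± 0.09 (adjusted p = 0.00911).

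Of 14874 genes tested, 441 changed with CHIR, 124 of them by at least 2-fold, and fewer changed in 1 fit over all libraries. Of the 441 genes 251 were higher and 190 lower. The count was 230 and 208 without CHIR replicate 1 or 2, and 218 and 268 without untreated replicate 1 or 2. Of 19 Wnt targets 9 rose and none fell (11 rose adjusted over the list alone), among them AXIN2, a feedback inhibitor, by 1.36 ± 0.12, the antagonist DKK4 by 3.64, the ubiquitin ligase RNF43 by 2.75 and LEF1, the partner of beta-catenin on DNA, by 1.72. Of 13 primitive streak genes 4 rose and none fell (7 adjusted over the list alone); WNT3 rose by 2.44 and TBXT (brachyury) by 2.24 ± 0.59 to only 2.96 CPM, while MIXL1 did not pass (1.17 ± 0.35, adjusted p = 0.0983). Both lists also passed the camera test with an estimated correlation (adjusted p = 0.019 and 0.0234). Of 18 pluripotency genes 3 rose and 5 fell (4 and 5 adjusted over the list alone); NANOG rose by 0.42, while PRDM14 fell by 0.93 and the methyltransferase DNMT3B by 0.79.

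Some cholesterol synthesis genes fell with CHIR: 6 of 22 fell and none rose (8 adjusted over the list alone), HMGCS1 by 1.03 ± 0.11 from 179 CPM, MSMO1 by 0.84 and IDI1 by 0.76, with list adjusted p = 2.01e-06 and 0.0577 with an estimated correlation. Among 22 p53 targets 3 rose (13 up and 1 down adjusted over the list alone), among them the antiproliferative BTG2 by 1.42 and PHLDA3 by 0.93 (list adjusted p = 0.0934 with an estimated correlation). Of 17 FGF and ERK targets 5 rose and 1 fell (5 and 2 adjusted over the list alone; 0.0934 with an estimated correlation), PHLDA1 by 1.07 and EPHA2 by 0.98 upward and ETV5 downward (-0.67). Of 19 stress-response genes of the unfolded protein and integrated pathways 3 rose (6 adjusted over the list alone; 0.0986 with an estimated correlation), including CHAC1 by 0.89. Of 24 G2 to M genes 2 fell (5 down and 1 up adjusted over the list alone; 0.233 with an estimated correlation), and of 5 lateral and cardiac mesoderm genes 1 fell (3 adjusted over the list alone; 0.0934). The BMP targets ID2 and ID3 rose by 1.30 and 0.58 while ID4 (-0.88) and BAMBI (-0.78) fell. Nodal and Activin targets were split, with 4 of 20 up and 4 down; their median was -0.16, their mean 0.37, and the list test, adjusted p = 0.624, pointed up.

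The largest changes included PROX1, a homeobox factor, up by 3.31 ± 0.57, ZEB2, a repressor of epithelial genes, up by 2.87, and LRRC17 up by 3.05. SHISA2, which holds back Wnt and FGF receptors, fell by 2.09 ± 0.28 from 33.1 to 7.77 CPM, CD248 fell by 2.21, the kinase SGK1 by 1.80 and the stem cell factor FOXD3 by 1.52 ± 0.22.

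**Figure D2:**
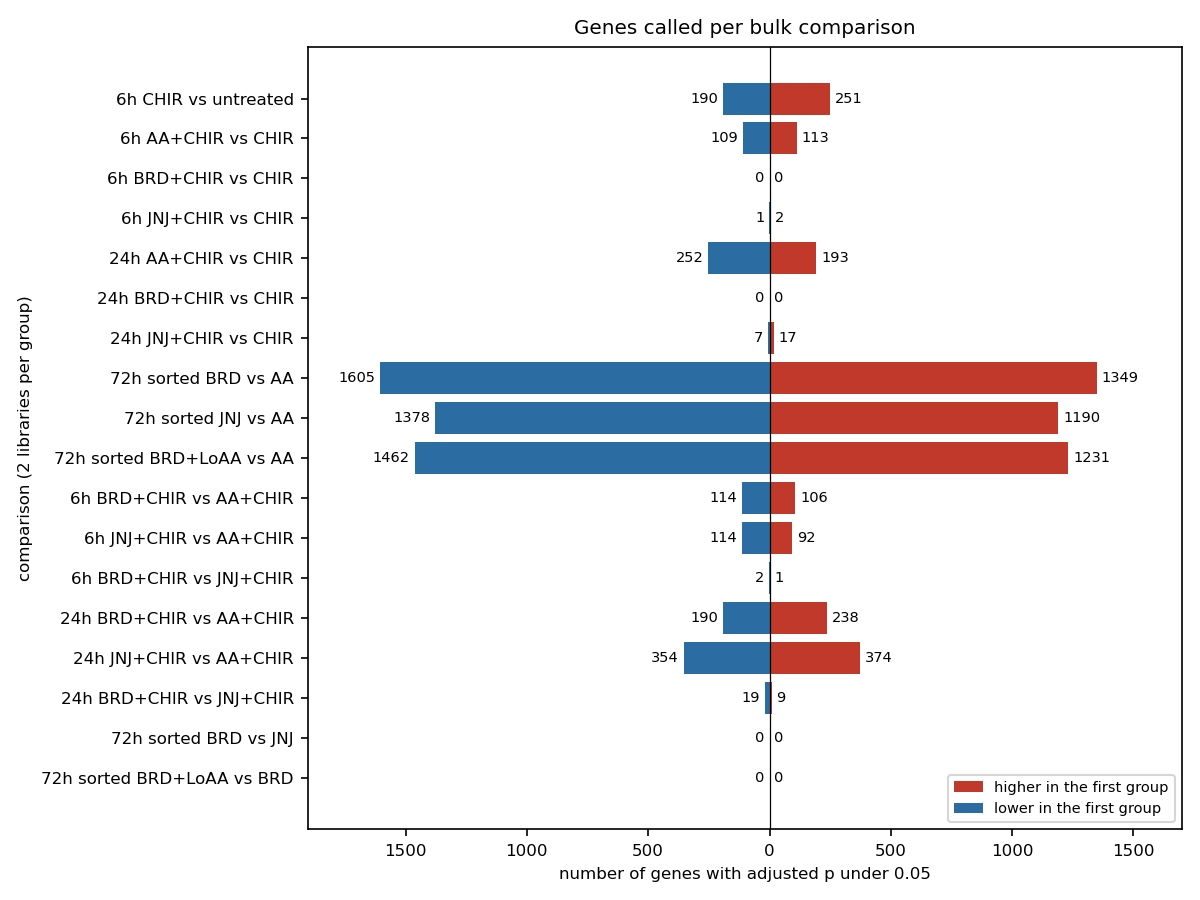
Number of genes higher (bars to the right) and lower (bars to the left) at a false discovery rate of 0.05 in 18 bulk comparisons between groups of 2 libraries. The sorted 72 h cells made with BRD instead of Activin A had 1349 genes higher and 1605 lower, and BRD with CHIR against CHIR alone at 6 h had 0.

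Activin A on top of CHIR at 6 h raised mesendoderm genes and Nodal feedback genes. MIXL1, a homeobox gene of the primitive streak, rose from 5.23 ± 1.5 to 79.7 ± 1.14 CPM (log2 change 3.93 ± 0.30, adjusted p = 4.50e-07), EOMES from 43.3 to 125 CPM (1.53 ± 0.15) and TBXT from 2.96 to 14.7 CPM (2.31 ± 0.49). The secreted Nodal inhibitors LEFTY1 and LEFTY2 rose by 3.28 ± 0.28 and 3.69 ± 0.50, and CER1, which binds Nodal and BMP, rose from 6.18 to 40.1 CPM (2.70 ± 0.29). ID1, a BMP and SMAD target, rose from 26.9 to 146 CPM (2.44 ± 0.14). SOX2 fell from 195 ± 4.49 to 82.7 ± 0.744 CPM (-1.24 ± 0.09), while AXIN2 (-0.32, adjusted p = 0.247), FOXA2 (0.45, adjusted p = 0.925) and POU5F1 (0.11, adjusted p = 0.628) did not pass.

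Activin A changed 222 genes at 6 h, 113 higher and 109 lower; the count was 80 without AA+CHIR replicate 1, and 65 and 72 without CHIR replicate 1 or 2. Of 20 Nodal and Activin targets 10 rose and 1 fell (14 and 1 adjusted over the list alone); NODAL itself rose by 0.82, the inhibitory SMAD7 by 1.05 and PMEPA1 by 0.92, and FST fell by 0.64. Of 13 primitive streak genes 5 rose (10 adjusted over the list alone), including FGF8, a streak growth factor, by 3.01. Of 14 BMP targets 4 rose (9 up and 1 down adjusted over the list alone): ID1, ID2 by 1.14, ID4 by 1.71 and BAMBI by 1.08. Each of these lists kept an adjusted p of 0.00346 with an estimated correlation. Of 18 pluripotency genes 1 rose and 3 fell (1 and 7 adjusted over the list alone; adjusted p = 0.00257, and 0.0561 with an estimated correlation), with NANOG up by 0.60. Wnt targets were split, 2 up and 2 down of 19; NKD1 rose by 0.67 and SP8 fell by 1.37. NOTUM, an enzyme that inactivates Wnt ligands, rose by 3.87 ± 0.83 to 7.90 CPM, and WNT5B and the Wnt receptor FZD7 fell by 1.70 and 1.14. The neural homeobox genes LHX4, GBX2 and IRX2 fell by 2.45, 2.46 and 1.81, and PRICKLE1, of the planar polarity pathway, fell by 2.25 ± 0.16. CDH2 (N-cadherin) rose by 0.71, PDK1, a brake on pyruvate oxidation, by 0.50, and the glycolysis genes HK2 and SLC2A1 fell by 0.55 and 0.41.

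With neither compound did the streak genes that Activin A raised at 6 h pass the test. With BRD in its place, MIXL1 stood at 4.75 ± 0.810 CPM against 5.23 ± 1.5 with CHIR alone, a log2 difference of -0.15 (95% interval -0.80 to 0.51), and EOMES differed by -0.19 (-0.51 to 0.13). With JNJ, MIXL1 differed from CHIR alone by -0.16 (-0.83 to 0.52) and EOMES by -0.22 (-0.55 to 0.11). NODAL lay slightly lower with BRD (-0.29, -0.52 to -0.06) and with JNJ (-0.24, -0.47 to -0.01). With BRD LEFTY1 lay at -0.03 (-0.63 to 0.57), CER1 at -0.23 (-0.86 to 0.41), SOX2 at -0.19 (-0.38 to -0.01) and POU5F1 at -0.01 (-0.16 to 0.13). These intervals are per gene and not adjusted.

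BRD changed 0 genes by edgeR at 6 h, with 452 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom; leaving out CHIR replicate 2 gave 4. JNJ changed 3 genes (703 at an unadjusted p under 0.05; 9 by DESeq2, 3 by limma-voom), with 5 without CHIR replicate 2 and 0 without JNJ replicate 2. DDIT4, a stress and hypoxia gene that restrains mTOR, rose from 54.7 ± 6.23 to 119 ± 1.72 CPM (1.13 ± 0.15, adjusted p = 0.00328), and KDM3A, a histone demethylase that hypoxia induces, from 37.0 to 79.0 CPM (1.09 ± 0.14). The third, RIMBP3, fell with an adjusted p of 0.0408 at a level near 0; it lies outside the naming rule and was chosen after its values were seen. Of 20 glycolysis and hypoxia genes 1 rose (6 adjusted over the list alone), with list adjusted p = 9.19e-08 and 0.142 with an estimated correlation. Among 11098 genes of at least 5 CPM, the 95% interval of the change lay inside 2-fold either way for 94.0% with BRD and 92.8% with JNJ.

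At 6 h few genes told the compounds apart. DDIT4 lay lower with BRD than with JNJ by a log2 difference of -1.19 (-1.49 to -0.89; adjusted p = 0.00279), and BNIP3, a mitophagy gene that hypoxia induces, by -0.66 (-0.85 to -0.47; adjusted p = 0.00678). These were 2 of the 3 genes called; SMIM11A, whose sequence is nearly shared with SMIM11B, was the other and its identity is uncertain. Leaving out BRD replicate 1 or 2 gave 1 and 2 genes, JNJ replicate 1 gave 0 and JNJ replicate 2 gave 5. BNIP3 lost its call in each of these fits, and DDIT4 without BRD replicate 2 or JNJ replicate 1. Of 20 glycolysis and hypoxia genes 1 was lower with BRD (5 adjusted over the list alone; adjusted p = 1.18e-07, and 0.147 with an estimated correlation); 4 of 26 lists passed, and 0 with an estimated correlation. EOMES differed between the compounds by 0.03 (-0.29 to 0.36), MIXL1 by 0.01 (-0.66 to 0.68) and SOX2 by -0.05 (-0.24 to 0.13).

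Set directly against Activin A at 6 h, both compounds left the streak program low. MIXL1 lay at a log2 difference of -4.07 ± 0.30 with BRD and -4.08 with JNJ, EOMES by -1.72 and -1.75, NODAL by -1.11 and -1.06, LEFTY1 by -3.31 and -3.01, and TBXT by -2.05 and -2.44. SOX2 was higher by 1.04 and 1.10, and PRICKLE1 by 2.38 and 2.39. BRD differed from Activin A at 220 genes (106 higher, 114 lower) and JNJ at 206 (92 higher, 114 lower). For BRD the count was 109 without AA+CHIR replicate 1, and 87 and 103 without BRD replicate 1 or 2; for JNJ it was 109 without AA+CHIR replicate 1 and 100 without JNJ replicate 1. With BRD 6 of 13 primitive streak genes and 11 of 20 Nodal and Activin targets were lower and none higher (8 lower, and 13 lower with 2 higher, adjusted over the list alone; adjusted p = 0.00403 for each with an estimated correlation). With JNJ 5 of 13 and 9 of 20 were lower, and 1 of the latter was higher (9, and 14 with 2 higher, adjusted over the list alone; adjusted p = 0.00465 for each with an estimated correlation). BMP targets were lower for both, 4 of 14 in each case (6 and 7 adjusted over the list alone; 0.00481 and 0.00465 with an estimated correlation).

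At 24 h Activin A raised streak genes and mesendoderm regulators above their level with CHIR alone. Untreated cells of 24 h were not analysed here, so the effect of CHIR alone was not tested at this time. MIXL1 stood at 518 ± 5.77 CPM with CHIR and 1060.5 ± 15.9 with AA+CHIR (log2 change 1.03 ± 0.10), EOMES at 320.2 ± 6.81 and 674 ± 39.5 (1.07 ± 0.11), and TBXT at 107 ± 3.30 and 212 ± 29.7 (0.99 ± 0.15). CER1 rose from 94.2 ± 12.0 to 1255 ± 116 CPM (3.74 ± 0.18, adjusted p = 3.33e-09), GATA6, an endoderm and mesoderm factor, from 20 to 171 CPM (3.09 ± 0.21), and LHX1, of the anterior streak, from 1.05 to 57.9 CPM (5.76 ± 0.86). FOXA2, the pioneer factor of endoderm, was lower with Activin A, at 18.4 ± 0.403 against 70.4 ± 16.2 CPM (-1.94 ± 0.21), as was LEFTY1 (-1.90 ± 0.33). SOX17, the endoderm factor, had 56 counts with AA+CHIR and 0 with CHIR and did not pass (adjusted p = 0.412), and CXCR4 had 0 counts in both groups.

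At 24 h Activin A changed 445 of 15586 genes, 193 higher and 252 lower; without AA+CHIR replicate 1 or 2 the count was 260 or 217, and without CHIR replicate 1 or 2 it was 253 or 203. The balance of directions was not stable, since limma-voom called 578, 315 higher and 263 lower. Larger counts still came from DESeq2 and from 1 fit over all libraries. Of 19 primitive streak genes 11 rose and none fell (11 up and 2 down adjusted over the list alone), among them GSC by 0.80, WNT3 by 0.92, FGF17 by 3.18, EVX1, of the posterior streak, by 2.31 and SNAI1, which drives cells out of the epithelium, by 1.42. Of 20 definitive endoderm genes 3 rose and 1 fell (6 and 1 adjusted over the list alone). Of 18 pluripotency genes 5 fell and none rose (8 down and 1 up adjusted over the list alone), with SOX2 down by 2.11 ± 0.17 to 7.69 CPM, NANOG by 1.23 and LIN28A by 0.41. These lists had adjusted p = 0.000737, 0.00313 and 0.00286, and each 0.0997 with an estimated correlation.

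Signalling genes moved too. Of 20 Wnt targets 4 rose (6 up and 1 down adjusted over the list alone; 0.219 with an estimated correlation), among them the antagonists DKK1, from 39.1 to 443 CPM, and DKK4, from 31.7 to 691 CPM (4.44 ± 0.22). Of 15 BMP targets 3 rose (5 adjusted over the list alone; 0.104 with an estimated correlation), including ID1 by 2.13, and the ligand BMP2 rose by 2.99. Of 20 Nodal and Activin targets 7 rose and 2 fell (9 and 4 adjusted over the list alone; adjusted p = 0.114); SMAD7 rose by 1.81, FST fell by 1.29, and NODAL did not pass (-0.04, adjusted p = 0.956). Their median was 0.04, their mean -0.03, and the test pointed up. Of 18 matrix and epithelial-mesenchymal genes 5 rose and 2 fell (7 and 3 adjusted over the list alone; 0.311 with an estimated correlation), COL5A2 by 1.75 and CDH2 by 0.61 upward, and CDH1 (E-cadherin) and EPCAM by -0.60 and -0.55. Of 7 gut genes 1 fell (2 adjusted over the list alone; 0.104 with an estimated correlation), of 24 G2 to M genes 2 rose (3 adjusted over the list alone; 0.104) and of 22 cholesterol genes 1 rose (0.292). The p53 list passed downward and the stress-response list upward without a called gene (0.219 and 0.104 with an estimated correlation).

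PDGFRA, a receptor of mesoderm and endoderm precursors, rose from 0.0906 to 91.2 ± 21 CPM (9.95 ± 0.91), MSX1, a BMP-dependent homeobox gene, by 7.90 ± 1.39, the apelin receptor APLNR by 3.76 and TBX6 by 2.43. MESP1, a factor of early mesoderm, had 610 counts with AA+CHIR and 0 with CHIR, at least 217-fold higher against a floor of 3 counts over the group. Zeros of this CHIR group are less sure than the floor takes them to be. In it 156 genes had 0 counts in 1 replicate and at least 50 in the other. ITGA6 fell by 1.99, DUSP6, an ERK phosphatase, by 1.28, KRT7 by 4.97 and SEMA3C by 3.22.

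At 24 h no streak gene passed with BRD against CHIR alone. EOMES differed by 0.04 (95% interval -0.19 to 0.27), while MIXL1 lay higher by 0.23 (0.03 to 0.44) and TBXT by 0.51 (0.19 to 0.82). SOX2 differed by -0.18 (-0.52 to 0.16), FOXA2 by -0.01 (-0.45 to 0.43) and CER1 by -0.62 (-0.96 to -0.27). These intervals are per gene and not adjusted for the number of genes. BRD changed 0 genes by edgeR, with 738 at an unadjusted p under 0.05, 17 by DESeq2 and 0 by limma-voom; leaving out CHIR replicate 1 or 2 gave 3 and 1, and leaving out BRD replicate 1 or 2 gave 3 and 4. The gut list alone passed (adjusted p = 0.0287, and 0.509 with an estimated correlation), with 0 of its genes called. The 95% interval lay inside 2-fold either way for 72.6% of 11336 genes of at least 5 CPM.

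JNJ at 24 h raised genes of glycolysis and hypoxia. LDHA, which turns pyruvate into lactate, rose from 498 ± 17.8 to 987 ± 74.5 CPM (0.99 ± 0.13), BNIP3 from 319 ± 21 to 733 ± 40.2 CPM (adjusted p = 0.000279), and the glucose transporter SLC2A1 from 185 to 327 CPM (0.82). The oxygen sensor EGLN1 rose by 1.35, the lactate transporter SLC16A3 by 2.13 ± 0.37, the collagen-modifying enzymes PLOD2 and P4HA1 by 1.26 and 1.07, HK2 by 0.93, PGK1 by 0.78, PDK1 by 0.77 and STC1, a secreted calcium regulator, by 1.85 ± 0.21. Of 20 genes on the list 8 rose and none fell (13 adjusted over the list alone), with adjusted p = 3.56e-12 and 0.0739 with an estimated correlation. Genes that fell included secreted factors: DKK4 from 31.7 ± 9.36 to 8.04 ± 2.35 CPM (-1.98 ± 0.21), CER1 from 94.2 to 30.3 CPM (-1.64 ± 0.17), DKK1 by 0.91 and FGF10 by 2.11, beside the hyaluronan synthase HAS2 by 1.25. EOMES (-0.06, 95% interval -0.29 to 0.17) and MIXL1 (-0.08, -0.29 to 0.12) did not pass.

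JNJ changed 24 genes at 24 h, 17 higher and 7 lower, with 1382 at an unadjusted p under 0.05. The balance of directions was not stable: DESeq2 called 146, 73 higher and 73 lower, and 1 fit over all libraries 286, 136 higher and 150 lower. Without JNJ replicate 1 the count was 31, 10 higher and 21 lower, without JNJ replicate 2 it was 12, 6 in each direction, and without CHIR replicate 1 or 2 it was 14 or 11. The JNJ group held the largest number of genes at 0 in 1 replicate with at least 50 counts in the other, 298.

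BRD and JNJ differed from each other at 28 genes at 24 h, 9 higher and 19 lower with BRD (1281 at an unadjusted p under 0.05); the count was 9 and 12 without BRD replicate 1 or 2 and 16 without JNJ replicate 2, and without JNJ replicate 1 it was 27, 18 higher and 9 lower. DESeq2 and 1 fit over all libraries called more genes, with more of them higher than lower with BRD, so this balance was not stable. With BRD, LDHA was lower by a log2 difference of -1.02 (-1.30 to -0.73), BNIP3 by -1.13 (-1.40 to -0.87), STC1 by -1.50 (-1.94 to -1.06), HK2 by -1.05 and PLOD2 by -1.19. Of 20 glycolysis and hypoxia genes 8 were lower (13 adjusted over the list alone), with adjusted p = 0.0452 with an estimated correlation. CER1 was higher with BRD by 1.02 (0.66 to 1.37), DKK4 by 2.19 (1.73 to 2.65), FGF10 by 2.26 and HAS2 by 1.19 (0.78 to 1.59). EOMES differed by 0.10 (-0.13 to 0.33) and SOX2 by 0.07 (-0.27 to 0.41).

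**Figure D3:**
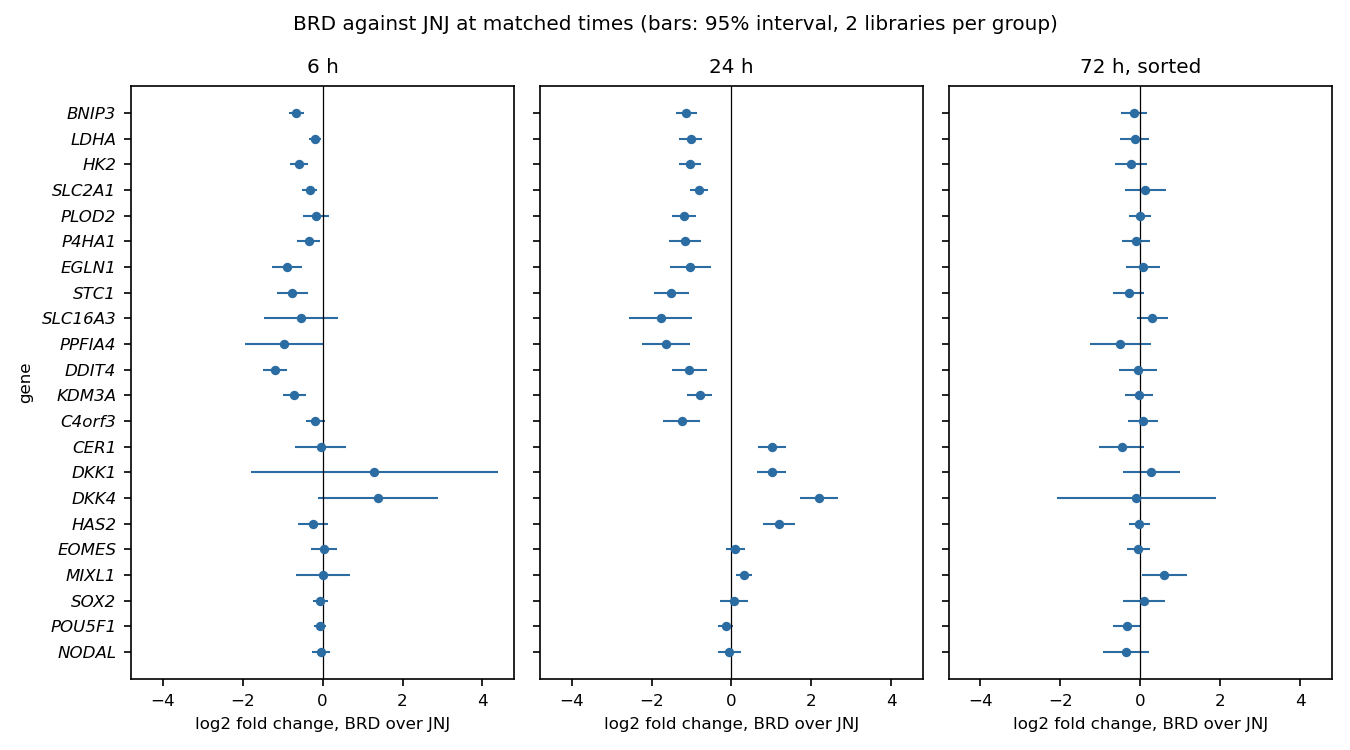
Log2 difference of BRD over JNJ with its 95% interval for 22 genes at 6 h and 24 h (both with CHIR) and in the 72 h sorted cells; each point is a fit over groups of 2 libraries and 0 means no difference. BNIP3 lay at -0.66 at 6 h and -1.13 at 24 h, and EOMES at 0.03 and 0.10.

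Against Activin A at 24 h, BRD differed at 428 genes (238 higher, 190 lower) and JNJ at 728 (374 higher, 354 lower). These balances were not stable: limma-voom gave 199 higher and 218 lower for BRD and 438 and 475 for JNJ. FOXA2 was higher with both compounds, by 1.93 and 1.92, as were LEFTY1 by 1.54 and 1.97 and SOX2 by 1.93 and 1.86, while EOMES was lower by -1.03 and -1.13, MIXL1 by -0.80 and -1.12 and GSC by -0.95 and -1.20. With BRD 1 of 20 definitive endoderm genes was higher and 5 lower (1 and 7 adjusted over the list alone), and 1 of 7 gut genes was higher (5 adjusted over the list alone), each with adjusted p = 0.042 with an estimated correlation. Of 19 streak genes 9 were lower with BRD and 10 with JNJ (0.0556 and 0.0804 with an estimated correlation), and with JNJ 10 of 20 glycolysis and hypoxia genes were higher (0.0804). For BRD the count was 259, 194, 226 and 198 without AA+CHIR replicate 1 or 2 or BRD replicate 1 or 2, and for JNJ 431 and 374 without AA+CHIR replicate 1 or 2.

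Sorted endoderm at 72 h carried SOX17 under every treatment, at a lower level where a compound took the place of Activin A. These cells were sorted as definitive endoderm, so endoderm genes in each arm cannot show how well a treatment made endoderm. SOX17 stood at 428 ± 13.3 CPM with Activin A, 258 ± 26.2 with BRD, 262 ± 19.4 with JNJ and 252 ± 14.4 with BRD and LoAA, log2 changes of -0.73 ± 0.13, -0.71 and -0.76. FOXA2 was higher, at 63.5, 59.9 and 55.5 CPM against 18.8 (1.76 ± 0.15, 1.67 and 1.57), and so was FOXA1 (3.20, 3.23 and 2.69). CXCR4, a surface receptor often used to sort endoderm, did not pass with BRD (-0.32, adjusted p = 0.185) or JNJ (-0.17, adjusted p = 0.538) and was lower with BRD and LoAA, at 89.2 against 144 ± 28.9 CPM (-0.70, adjusted p = 0.00857). CER1 dropped from 4437 ± 451 to 76.2 ± 29.5 CPM with BRD (-5.85 ± 0.30), 106 with JNJ and 74.1 with BRD and LoAA.

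BRD differed from Activin A at 2954 of 13889 genes (1349 higher, 1605 lower, 1506 by at least 2-fold), JNJ at 2568 (1190 higher, 1378 lower) and BRD with LoAA at 2693 (1231 higher, 1462 lower). Without Activin A replicate 1 or 2 the counts were 1607 and 1785 for BRD, 1420 and 1537 for JNJ, and 1348 and 1544 for BRD with LoAA, which had 1635 without its own replicate 2. The calls overlapped: 1012 genes were higher and 1208 lower with both BRD and JNJ, and 1 changed in opposite directions, where independent calls would share 116 and 159. Across 11610 genes, which are not independent replicates, the changes with BRD and JNJ had Pearson r = 0.941. In 20 simulated draws with shared controls and no change in any group, the mean r was 0.510. These draws do not give the r of arms that each change, but in different genes. The covariance of the changes was 0.668, against a mean of 0.0455 in the draws. With 1 Activin A library for each comparison, a setting added later, 529 genes were higher and 624 lower with both (517 and 601 with the libraries exchanged), where independent calls would share 40.1 and 46.5 (41.0 and 48.0), and r was 0.771 and 0.763. Part of the excess with both libraries may come from the shared controls.

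NODAL and the LEFTY genes fell with the compounds. Of 17 Nodal and Activin targets 3 rose and 10 fell with BRD (4 and 10 adjusted over the list alone; adjusted p = 0.00223, and 0.192 with an estimated correlation), 2 rose and 10 fell with JNJ (0.238) and 3 rose and 10 fell with BRD and LoAA (0.182). NODAL dropped from 216 ± 34.8 to 15.6 ± 0.739 CPM with BRD (-3.79 ± 0.26) and LEFTY1 from 178 to 2.06 CPM (-6.41 ± 0.38). LEFTY2 dropped from 420.2 ± 122 to 0.283 CPM (-10.37 ± 0.36). That level lies near the floor of 3 counts over the BRD group (0.224 CPM), so the size of the LEFTY2 change is less certain than its SE. LEFTY2 had 1 count with BRD and LoAA. PMEPA1 fell by 1.97 and FST by 1.30. Of 13 streak genes 3 rose and 6 fell (3 and 7 adjusted over the list alone; adjusted p = 0.17): MIXL1 fell by 2.31, GSC by 1.44, EOMES by 0.90 and FGF17 by 2.83, while TBXT rose by 1.94 to 11.2 CPM and EVX1 by 4.84.

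Endoderm genes went both ways. Of 22 definitive endoderm genes 5 rose and 11 fell with BRD (the same counts adjusted over the list alone; adjusted p = 0.0715, and 0.488 with an estimated correlation), and 5 rose and 13 fell with BRD and LoAA (6 and 13 adjusted over the list alone; 0.461). With BRD, GATA6 fell by 1.17, GATA4 by 0.82, the scavenger receptor COLEC12 by 3.06 and RHOBTB3 by 2.07, while the receptor KIT rose by 0.98 from 305 to 601 CPM. STC1 fell from 1668 ± 52.6 to 28.7 ± 8.59 CPM (-5.84 ± 0.20). HNF4A, a liver and gut regulator, rose by 3.05 to 15.2 CPM, and LGR5, a stem cell receptor for R-spondin, rose by 2.31.

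More BMP targets rose than fell, while Wnt targets and pluripotency genes went both ways. Of 14 BMP targets 9 rose and 2 fell with BRD (11 and 2 adjusted over the list alone; adjusted p = 2.34e-05, and 0.192 with an estimated correlation), with ID1 up by 2.37, ID4 by 3.03 and SMAD9 by 4.52; the ligand BMP4 fell by 1.18. GATA3, a factor of amnion, trophoblast and surface ectoderm, rose from 6.18 ± 2.53 to 138 ± 27.0 CPM (4.55 ± 0.24), TBX3 by 4.09 and ISL1 by 4.40. Wnt targets were split, 6 up and 3 down of 18 (7 and 4 adjusted over the list alone; adjusted p = 0.114), with SP5 up by 3.55, DKK1 by 4.05 and CCND1 by 1.78 and AXIN2 down by 1.11. SOX2 rose from 1.61 ± 0.620 to 20.8 ± 0.126 CPM (3.61 ± 0.32), POU5F1 from 63.3 to 127 CPM (1.01) and ZFP42 by 1.63, but 3 of 16 pluripotency genes fell against 5 that rose (the same adjusted over the list alone; adjusted p = 0.0715). The list passed with JNJ (5 up, 1 down; 7 and 1 adjusted over the list alone; adjusted p = 0.0297, and 0.238 with an estimated correlation) and with BRD and LoAA (7 up, 1 down; adjusted p = 0.0427, and 0.257).

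Cell cycle and metabolic genes changed too, though none of the 26 fixed lists passed with an estimated correlation for BRD. All 24 G2 to M genes fell with BRD (all 24 adjusted over the list alone; adjusted p = 1.26e-12, and 0.294 with an estimated correlation) and with JNJ (0.238), and 22 of 24 with BRD and LoAA (24 adjusted over the list alone; 0.257 with an estimated correlation). UBE2C, of the mitotic ubiquitin ligase, fell by 1.52, the kinase AURKA by 1.19 and MKI67 by 0.99. Of 24 G1 to S genes 8 rose and none fell (8 adjusted over the list alone; 0.488), MCM4 and MCM2 of the replication helicase by 1.03 and 0.93. Of 22 cholesterol genes 16 fell and 1 rose (19 and 1 adjusted over the list alone; 0.335), with HMGCS1 down by 2.06 from 1149 CPM and ACAT2 by 1.56. Of 19 stress-response genes 14 fell (15 adjusted over the list alone; 0.192), ASNS by 1.84, CHAC1 by 3.28 and ATF4 by 0.92. Of 19 glycolysis and hypoxia genes 6 rose (7 adjusted over the list alone; 0.39), ADM by 2.45, SLC2A1 by 2.02 and HK2 by 1.48. Of 16 FGF and ERK targets 8 fell and 1 rose (10 and 2 adjusted over the list alone; 0.39), with MYC down by 2.23 and DUSP4 by 1.80.

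Adhesion genes changed without a common direction, 6 up and 6 down of 17 matrix and epithelial-mesenchymal genes (6 and 7 adjusted over the list alone; adjusted p = 0.547). COL5A2 fell from 1003 ± 17.7 to 20.8 ± 5.50 CPM (-5.57 ± 0.20), VIM (vimentin) by 2.93 and ZEB2 by 5.52, while FN1 (fibronectin) rose by 2.47 and CDH1 by 1.70. KLHL14 was at least 56.4-fold higher with BRD, the apelin-receptor ligand APELA at least 50.7-fold and GATA5 at least 12.7-fold, each against 0 counts with Activin A; the fatty acid elongase ELOVL2 was at least 120-fold lower, GYPB at least 90.6-fold and WT1 at least 28.4-fold. Amnion and trophoblast genes (3 up, 2 down of 6; adjusted p = 0.309), extraembryonic endoderm genes (3 up, 1 down of 11; 0.309), lateral and cardiac genes (3 up, 2 down of 10; 0.384) and neuroectoderm genes (2 up, 1 down of 4; 0.607) did not pass as lists; the median of the last was 1.18 and its mean -0.60.

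**Figure D4:**
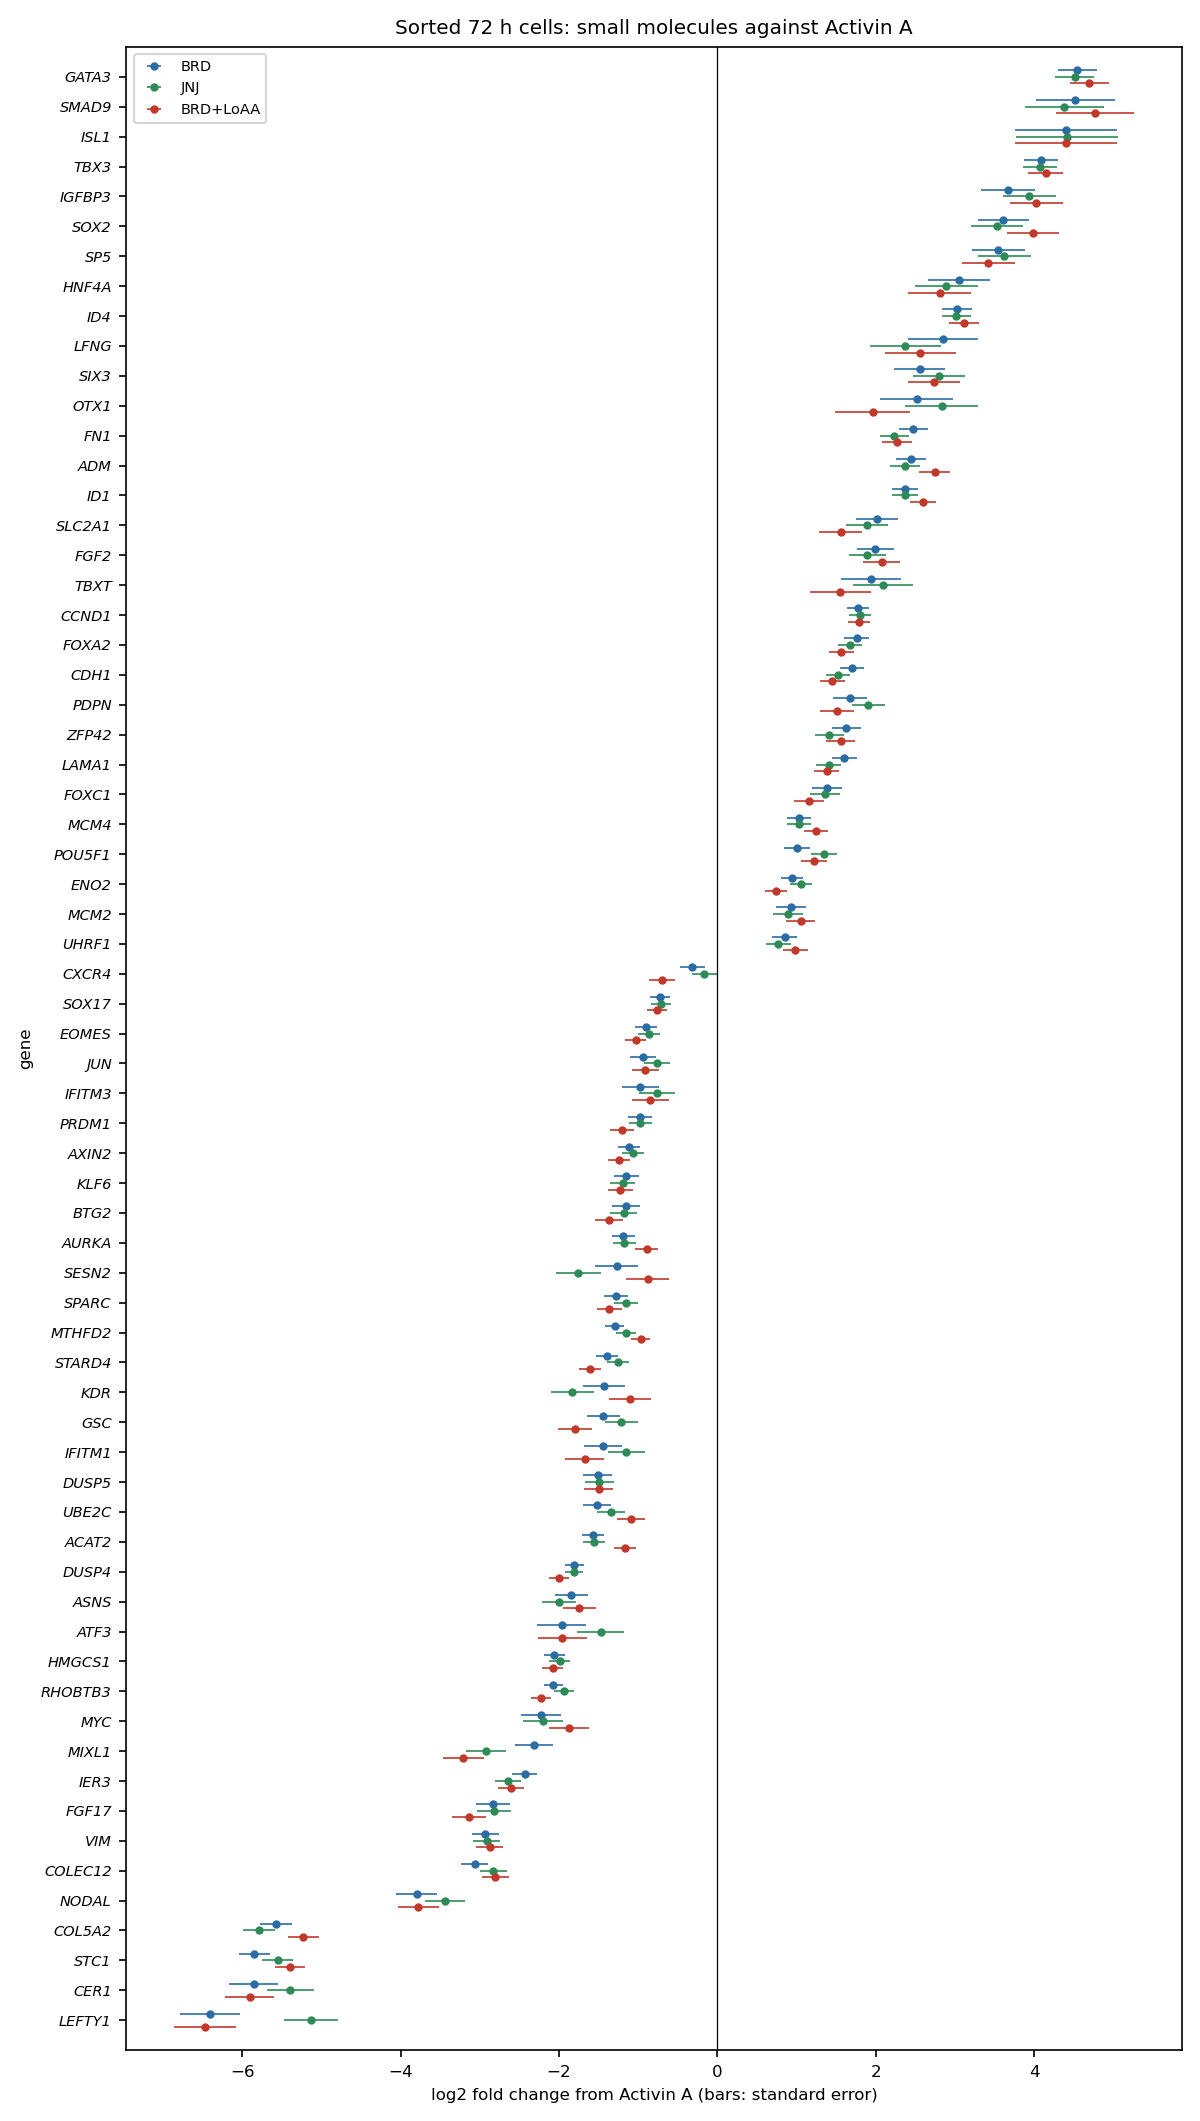
Log2 change from Activin A, with standard error, of named genes in the 72 h sorted cells made with BRD, JNJ or BRD with LoAA; each point compares 2 libraries with 2. SOX17 lay at -0.73, -0.71 and -0.76, and FOXA2 at 1.76, 1.67 and 1.57.

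The compounds differed little from each other in sorted cells. SOX17 differed between BRD and JNJ by a log2 difference of -0.02 (95% interval -0.29 to 0.26), FOXA2 by 0.08 (-0.22 to 0.39), CXCR4 by -0.15 (-0.49 to 0.19), SOX2 by 0.08 (-0.44 to 0.61) and NODAL by -0.36 (-0.94 to 0.23). LEFTY1 lay lower with BRD (-1.28, -2.34 to -0.22) and MIXL1 higher (0.61, 0.05 to 1.17), neither past adjustment. By edgeR 0 genes were called, with 390 at an unadjusted p under 0.05 and 4 by DESeq2; leaving out BRD replicate 1 or 2 gave 3 and 1, and leaving out JNJ replicate 1 gave 1. For 82.4% of 11610 genes of at least 5 CPM the interval lay inside 2-fold either way. The ribosomal protein list passed (adjusted p = 0.0236, and 0.763 with an estimated correlation).

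Nodal genes stayed low when LoAA was added to BRD. NODAL differed by 0.02 (-0.59 to 0.63), CER1 by -0.05 (-0.63 to 0.52), SOX17 by -0.03 (-0.31 to 0.24) and FOXA2 by -0.19 (-0.50 to 0.11); MIXL1 lay lower (-0.90, -1.47 to -0.32), as did CXCR4 (-0.38, -0.73 to -0.03) and SLC16A3 (-0.94, -1.34 to -0.53). By edgeR 0 genes were called, with 740 at an unadjusted p under 0.05 and 5 by DESeq2; leaving out BRD replicate 1 or 2 gave 1 and 2, and BRD with LoAA replicate 1 gave 1. G2 to M, G1 to S, and glycolysis and hypoxia genes passed as lists (adjusted p = 1.19e-05, 0.000279 and 0.00143), each with 0.585 under an estimated correlation and 0 genes called.

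Streak genes were low in the libraries of BRD alone, without CHIR. At 24 h EOMES stood at 0.0441 ± 0.0624 CPM with BRD alone and 329.5 ± 15.7 with BRD and CHIR, MIXL1 at 1.32 and 608, and FOXA2 at 0 and 70.0 ± 2.55, at least 1207-fold higher with CHIR. SOX2 was lower with CHIR, at 29.2 against 426 ± 45.1 CPM (-3.87 ± 0.17). At 6 h SP5 had 0 counts with BRD alone and 53.8 ± 7.15 CPM with BRD and CHIR, at least 371-fold higher, and against untreated cells SP5 was at least 37.9-fold lower, EOMES lay at a log2 change of -4.56 ± 0.44 and NODAL at -1.89. BRD alone differed from untreated cells at 8049 genes (3938 higher, 4111 lower). BRD with CHIR differed from BRD alone at 8020 genes at 6 h and 5531 at 24 h. In both 6 h comparisons the direction with more calls turned with RLE size factors, limma-voom or DESeq2. The BRD-alone libraries belong to another library series than the groups they were compared with. Treatment and series therefore cannot be told apart for these counts, nor for the gene and list values of BRD alone given here. The ribosomal protein list was among those that moved (1 up, 18 down of 20 against untreated cells; 0.376 with an estimated correlation). At 24 h 15 streak genes were higher with CHIR and none lower (0.0132 with an estimated correlation).

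The single-cell libraries were cells at 36 h (given as primitive streak cells), at 72 h after AA and CHIR (Endo) and at 72 h in a mesoderm induction medium (Meso). Of 6244, 6321 and 6266 barcodes 4193, 4511 and 5632 passed the filters, with median UMI counts of 21152, 7680 and 7873.5 per cell. There was 1 library per condition, so the values below carry counting intervals and no test between conditions.

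CER1, SOX17 and LEFTY1 set Endo cells apart from Meso cells. CER1 stood at 2963 CPM (95% interval 2944 to 2981) in Endo, 139 at 36 h and 0.0887 in Meso. SOX17 stood at 122 CPM in Endo with 0 counts in both others, at least 1838-fold over Meso, and LEFTY1 at 879 CPM with 0 in Meso, at least 13220-fold. LHX1 (986 against 1.06 CPM), OTX2 (325 against 0.710), EOMES (272 against 4.19), GATA6 (158 against 18.8), FOXA2 (28.7 against 0.821) and HHEX (58.7 against 0.0222) were higher in Endo than in Meso. With every cell thinned to 2000 UMIs, CER1 was seen in 92.6% of Endo cells (91.7 to 93.4), 13.1% at 36 h and 0% in Meso (0 to 0.0666), SOX17 in 20.5% (19.2 to 21.8), 0% (0 to 0.108) and 0%, and CXCR4 in 22.8% of Endo and 11.5% of Meso cells.

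TBXT, HOXB1 and CDX2 were higher in Meso than in Endo. TBXT stood at 326 CPM against 3.05 in Endo and was seen in 45% of thinned cells against 0.461%. HOXB1 (92.8 CPM), an early HOX gene, had 0 counts in Endo, at least 1045-fold higher in Meso, and CDX2, a posterior regulator, stood at 77.9 CPM against 0.0888. MSX1 (197 against 2.13), APLNR (121 against 4.32), TBX6 (82.1 against 7.58) and DKK1 (1381 against 6.10) were also higher in Meso. MIXL1 was seen in 35.0% of Meso, 21.1% of Endo and 17.4% of 36 h cells.

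POU5F1 and SOX2 were seen in more cells at 36 h than in Endo. POU5F1 stood at 995 CPM against 310.0 in Endo and was seen in 84.7% of thinned cells against 40.9%, and SOX2 in 8.20% against 1.14%. NODAL stood at 237 CPM, close to its 199.97 in Endo, GDF3 at 48.2 against 2.07, and CCND1 at 190 against 15.7. SFRP2, a secreted Wnt modulator, stood at 242 against 22.3 CPM.

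**Figure D5:**
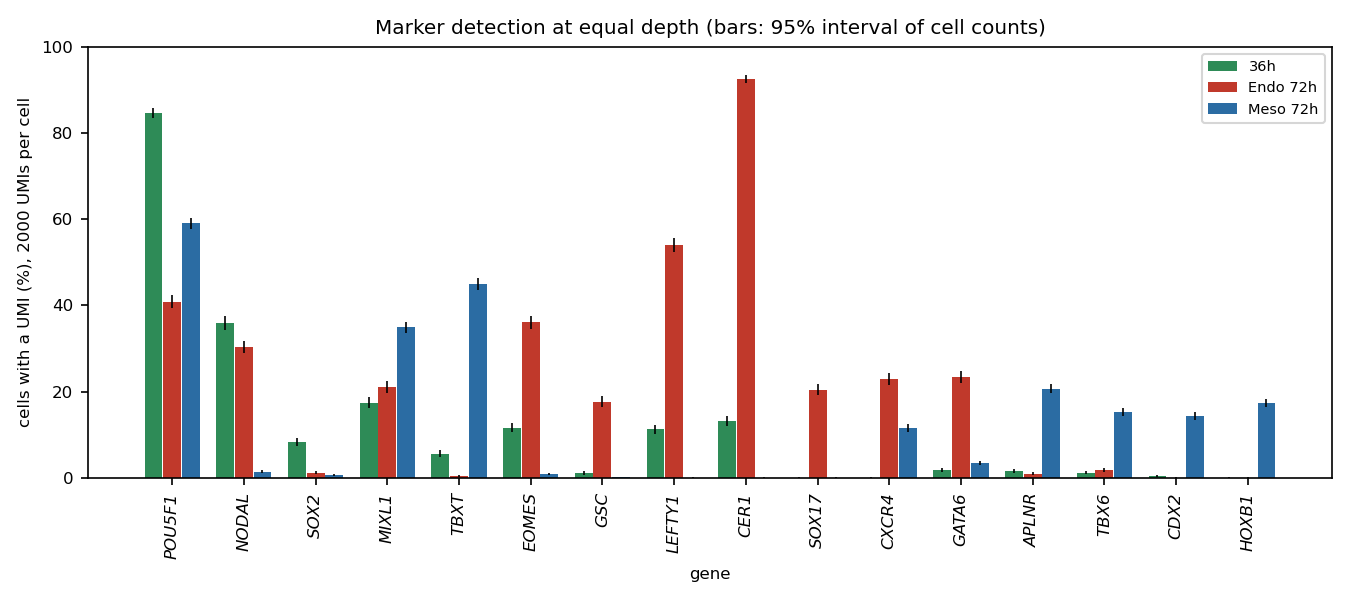
Percent of cells with at least 1 UMI of each of 16 genes after thinning every cell to 2000 UMIs, in the 36 h, Endo and Meso libraries, with 95% exact intervals; there is 1 library per condition. CER1 was seen in 13.1%, 92.6% and 0% of cells.

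Clustering gave 7 clusters at 36 h, 7 in Endo and 5 in Meso. Of the Endo cells 59.8% (2698 of 4511; 95% interval 58.4 to 61.2) lay in 3 clusters that the fixed markers named definitive endoderm-like, with SOX17 in 26.4%, 24.5% and 23.5% of their thinned cells. The share was 43.3% with no cell filter, and when thinned cells were clustered no cluster received that name (0 of 3685 cells). Clusters of 1071 (23.7%) and 206 cells (4.57%) stayed unnamed for low depth without a leading marker, with medians of 2108 and 1380.5 UMIs. CER1 was seen in 97.3% and 91.2% of their thinned cells, and SOX17 in 12.2% and 20.6%. The 59.8% is therefore no count of all cells with endoderm genes. A cluster of 404 cells (8.96%) was led by SOX2. It had SOX2 in 9.45% (6.42 to 13.3) of 307 thinned cells against 0% to 0.392% in the endoderm-like clusters, and SOX17 in 2.61%. CER1 was seen in 59.0% and LEFTY1 in 23.8% of the same thinned cells, both less often than in the endoderm-like clusters. Its median was 3596 UMIs against 9748 to 11867 in those clusters. Of the Meso cells 28.2% (27.1 to 29.4) were named lateral and cardiac mesoderm-like in a cluster led by cycling genes, a name that was kept with 1000 variable genes (24.7%) and 15 components (28.7%) and lost with no cell filter, with doublets kept, at Leiden resolutions 0.3 and 1.0, with thinned cells and without the top 5% of doublet scores. At 36 h 0 of 4193 clustered cells received a name; a lead over the next cell type, added to the naming rule after the clusters were seen, took it from 67.1% of them. By the rule tried first 43.6% were pluripotent-like and 23.5% primitive streak-like, and with the lead 94.6% were pluripotent-like with thinned cells and 42.1% with no cell filter. A cluster of 238 cells there (5.68%), led by LHX1, DKK4, APLNR, DKK1, GATA6, FGF17 and CER1, had CER1 in 82.5% of thinned cells against 5.79% in the largest cluster.

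Genes that set Endo apart from Meso in single cells were followed in bulk, as signatures taken from these samples and therefore not independent of them. In 72 h sorted cells 57 of 82 Endo genes fell and 3 rose with BRD relative to Activin A (60 and 3 adjusted over the list alone; adjusted p = 4.46e-22, and 0.022 with an estimated correlation), 55 fell and 4 rose with JNJ (0.0196) and 60 fell and 2 rose with BRD and LoAA (0.0205). Of 81 Meso genes 28 rose and 7 fell with BRD (29 and 7 adjusted over the list alone; adjusted p = 8.59e-05, and 0.022). At 6 h 22 of 85 Meso genes rose with CHIR and none fell (26 adjusted over the list alone; 0.000353 with an estimated correlation), and Activin A then raised 11 of 75 Endo genes and lowered 1 (13 and 4 adjusted over the list alone; 0.0385). At 24 h Activin A raised 18 of 80 Endo genes and lowered 5 (27 and 7 adjusted over the list alone; adjusted p = 1.69e-08, and 0.064 with an estimated correlation). Genes higher at 36 h than in both 72 h libraries were 9 up and 22 down of 94 with BRD at 72 h and did not pass as a list (11 and 26 adjusted over the list alone; adjusted p = 0.0534).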

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

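Of the tests in this part, the library-series test of BRD alone and the free-RNA test of mNeonGreen were set out before their result was seen, the tests of differences between time points were planned, and the other tests were chosen after the result was seen.

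The effect of Activin A on top of CHIR differed between 6 h and 24 h at 298 of 15717 genes in a test of the difference itself, 97 with a larger and 201 with a smaller log2 change at 24 h. The count was 183 without AA+CHIR replicate 1 of 6 h, and 171 and 161 without CHIR replicate 1 or 2 of 6 h. The log2 change of MIXL1 was smaller at 24 h, by -2.89 ± 0.26 (SE). That of LEFTY1 differed by -5.18 and turned from 3.28 to -1.90, and that of NODAL differed by -0.85, from 0.82 to -0.04, which did not pass at 24 h. For GSC (-2.44) the change at 6 h had not passed, and for POU5F1 (-0.39) it passed at neither time. SOX2 fell further at 24 h (-0.87). The log2 change of WNT5A, a Wnt ligand of the posterior streak, differed by 4.78; at 24 h it was 3.57, from 4.03 to 48.2 CPM. That of PDGFRA differed by 10.13. PDGFRA lay near the floor of 3 counts with CHIR at 24 h, and GSC had 5 counts with CHIR at 6 h. The differences of PDGFRA and GSC are therefore uncertain in size. The fitted differences of APOL3 (15.37), APLN, the ligand of the apelin receptor (11.32), GAS2 (-10.34), MFSD6 (-9.21), MINDY4 (-9.01) and the readthrough gene ARPC4-TTLL3 (-8.88) rest on a group with 0 counts, depend on the prior count and are no bounds. Libraries of 24 h often held genes at 0 in 1 replicate only, and these low-level genes were not tested apart from that. The groups compared are of series 33 at 6 h and series 38 at 24 h. A shift common to a series cancels within each time, but any other series effect cannot be told apart from time. The joint fit shares a common biological coefficient of variation of 0.281, against 0.140 at 6 h and 0.406 at 24 h.

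For BRD the effect differed between times at 1 gene, GCNT4 (-7.23), and for JNJ at 1 gene, TMEM37 (-8.32), each with 0 counts in the 24 h group with the compound, so neither value is a bound. For BRD the count was 0 without CHIR replicate 1 of 6 h, BRD replicate 2 of 6 h or BRD replicate 1 of 24 h, 2 without CHIR replicate 2 of 6 h, 5 and 6 without CHIR replicate 1 or 2 of 24 h, and 6 without BRD replicate 2 of 24 h. For JNJ it was 0 and 2 without CHIR replicate 1 or 2 of 6 h, 11 and 15 without CHIR replicate 1 or 2 of 24 h, and 138 and 18 without JNJ replicate 1 or 2 of 24 h. The causes were not tested.

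The feature table of the single-cell libraries holds mNeonGreen, a fluorescent protein that the human genome lacks and the labels do not mention, and its UMIs appeared in 34.7% of thinned Endo cells (1279 of 3685) against 2 of 3416 cells at 36 h and 0 of 5533 Meso cells. The tables argue against free RNA spread over the Endo library as the whole cause: 36.8% of the endoderm-like cells held an mNeonGreen UMI at equal depth, against 2.61% (95% interval 1.13 to 5.07) in the SOX2-led cluster, whose cells are shallower. The other clusters held 47.8% (590 thinned cells), 26.5% (34) and 8.62% (116). The first of these, with a median of 2108 UMIs, has the largest share of all, so a part from free RNA in shallow cells stays open. Among cells with an mNeonGreen UMI 26.7% also held a SOX17 UMI, against 17.1% of the rest. A candidate explanation that stays open is a reporter expressed along with endoderm genes. The design names no group for it, so no biological explanation was tested further.

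The sorted 72 h cells made with the compounds differed from those made with Activin A at 2568 to 2954 genes. The tables argue against a few genes taking most counts. The 10 top genes took 11.6% to 12.8% of the counts with BRD and with Activin A. Before TMM scaling this can shift all other genes by a log2 of at most 0.0199, while the smallest change called was 0.355. The TMM factors differed more, at 0.922 and 0.934 with Activin A against 1.05 and 1.01 with BRD. The bound therefore covers the 10 top genes only. Endoderm diluted by cells without endoderm genes stays open. Such dilution alone could not raise the 5 definitive endoderm genes that rose with BRD. It could act beside other changes, and other genes of that list fell, so the test cannot decide. Undifferentiated cells left in the sort stay open for the rise of SOX2. A share of 7.35% of untreated cells (7.93% of cells with BRD alone) would be enough. Of the pluripotency genes with at least 50 CPM in untreated cells, 0 lay below the level this share would bring. That count says little, since the Activin A sort itself lay above this level for many of them. DNMT3B stood there at 215 CPM where 116 would be needed, and L1TD1 at 446 where 163 would be. ZFP42 stood below it, at 20.9 CPM where 23.9 would be needed. With BRD, DNMT3B (155 CPM) and L1TD1 (280) were lower than with Activin A, while POU5F1 and ZFP42 were higher. Under the limit of 50 CPM, FOXD3 lay at 1.28 CPM where 2.30 would be needed, and UTF1 had 0 CPM where 0.52 would be needed. These values do not decide. Lower expression of Nodal and Activin targets could not be settled, with an adjusted p of 0.192 under an estimated correlation. The treatment itself, which the design names, stays open and untested as a cause.

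BRD alone differed from untreated cells at 8049 genes at 6 h. BRD acting as it does on top of CHIR is argued against as the cause of most of these changes. Over these genes the slope of BRD with CHIR against CHIR on BRD alone against untreated was 0.0131. A slope near 0 could be foreseen, since BRD on top of CHIR changed 0 genes at 6 h. The test does not cover an effect that BRD has only without CHIR. A difference between library series stays open: across 11098 genes, which are not independent replicates, the change from untreated to BRD alone went with the change from AA+CHIR at 24 h to sorted cells at 72 h, a step between series without BRD, with r = 0.364. That step also differs in time and sorting. Compound and series cannot be told apart, because every BRD-alone library is of series 46 and every other library of 6 h and 24 h is not.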

How the results depend on the processing

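Fits without the BRD-alone libraries or without the high-count genes, the thinned clusters, the removal of top doublet scores, the first naming rule and the overlaps with 1 control library for each comparison were chosen after the data were seen; the other alternatives were planned. No named gene reversed. Of 656 named results 596 were called; 3 lost their call with RLE size factors, 1 without a filter, 24 with a replicate block, 60 with limma-voom (1 gained it) and 88 in 1 fit over all libraries (3 gained it); with DESeq2 24 of the 596 lost it and 2 results gained it. None of 577 calls was lost under the stricter filter, none of 594 without the high-count genes, and 10 of 256 without the BRD-alone libraries (1 result gained it). Leaving out 1 replicate ended 510 of 2448 calls, counted over all such fits. With an estimated correlation 116 of 133 called list results and 14 of 28 called signature results lost their call, and with signatures of 50 genes 5 of 28 lost it and 6 others gained it. Without thinning, 238 of 333 shares of cells with a UMI moved beyond their interval.

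Where not named here, counts of genes stayed within 1.5 times the count reported. In 1 fit over all libraries, which shares the spread between times, 186 genes changed with CHIR and 91 with Activin A at 6 h. At 24 h 1157 changed with Activin A, 26 with BRD and 286 with JNJ. Against Activin A it gave 98 for BRD and 102 for JNJ at 6 h, and 1060 and 1822 at 24 h. BRD against JNJ gave 1, 256 and 1 at 6 h, 24 h and 72 h, and the time difference of JNJ gave 9. The wider spread of 24 h enters the 6 h tests in that fit. With 1 Activin A library for each comparison, the genes that changed alike with BRD and JNJ at 72 h went from 1012 higher and 1208 lower to 529 and 624, or 517 and 601.

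DESeq2 called 1 gene for BRD and 9 for JNJ at 6 h, and 729, 17 and 146 for Activin A, BRD and JNJ at 24 h. Against Activin A it called 331 and 340 for BRD and JNJ at 6 h and 708 and 1183 at 24 h. BRD against JNJ gave 12, 138 and 4, BRD with LoAA against BRD 5, and the time differences of Activin A, BRD and JNJ 550, 13 and 77. Without a filter BRD against JNJ gave 7 at 6 h and 4 at 72 h. Without the BRD-alone libraries JNJ changed 55 genes at 24 h, BRD against JNJ gave 49, and the time differences of BRD and JNJ gave 0 and 7. Limma-voom gave 0 and 3 for those time differences, and a replicate block gave 2 for JNJ. The direction with more calls turned in BRD against JNJ at 24 h (79 higher and 59 lower by DESeq2, 138 and 118 in 1 fit over all libraries), and in both 6 h comparisons of BRD alone with RLE size factors, limma-voom or DESeq2. It also turned for BRD against Activin A at 6 h under the stricter filter (130 and 123), for Activin A, and for BRD and JNJ against it, at 6 h without AA+CHIR replicate 2, and for JNJ against it at 24 h without JNJ replicate 1 (300 and 312). The causes were not tested. With a replicate block 402 genes changed with CHIR at 6 h (396 shared with the 441) and 2654 with BRD at 72 h (2625 shared). Replicate numbers showed no pairing at 6 h (correlations from -0.058 to 0.032) or 24 h (-0.033 to 0.027). At 72 h same-numbered replicates deviated alike for BRD and JNJ (0.175). Those of BRD with LoAA deviated the opposite way from BRD (-0.155) and JNJ (-0.142). A block by replicate number cannot take out a deviation that runs opposite ways between arms, and its cause was not tested.

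Leaving out 1 replicate left 208 to 268 genes for CHIR at 6 h, 65 to 155 for Activin A, 0 to 4 for BRD and 0 to 5 for JNJ. At 24 h it left 203 to 260 for Activin A, 1 to 4 for BRD and 11 to 31 for JNJ. At 72 h it left 1607 to 2326 for BRD, 1420 to 1807 for JNJ and 1348 to 1802 for BRD with LoAA. Against Activin A the ranges were 87 to 191 for BRD and 100 to 178 for JNJ at 6 h, and 194 to 259 and 374 to 612 at 24 h. BRD against JNJ gave 0 to 5, 9 to 27 and 0 to 3 at 6 h, 24 h and 72 h, and BRD with LoAA against BRD 0 to 2. BRD alone against untreated gave 6615 to 7224, and BRD with CHIR against BRD alone 6518 to 7002 at 6 h and 4262 to 4516 at 24 h. The time differences gave 161 to 336 for Activin A, 0 to 6 for BRD and 0 to 138 for JNJ. These fits have fewer samples.

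Shares of named cells depended on the clustering. At 36 h the pluripotent-like share, 0% as reported, was 42.1% with no cell filter, 94.6% with thinned cells and 43.6% by the first naming rule, which also named 23.5% primitive streak-like. The definitive endoderm-like share of Endo, 59.8%, was 43.3% with no cell filter, 49.5% at Leiden resolution 1.0, 49.7% with 15 components and 0% with thinned cells; with thinned cells 6.32% were primitive streak-like and 2.06% pluripotent-like, and by the first rule 11.9% were pluripotent-like. The lateral and cardiac mesoderm-like share of Meso, 28.2%, was 0% with no cell filter, with doublets kept, at Leiden resolutions 0.3 and 1.0, with thinned cells and without the top 5% of doublet scores, 24.7% with 1000 variable genes and 59.5% by the first rule. Its primitive streak-like share was 31.7% with thinned cells and 38.4% by the first rule. The causes were not tested. Depth limits what single cells show: at 2000 UMIs, SOX17 at 122 CPM was seen in 20.5% of Endo cells.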

Other observations

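Genes that marked Endo in single cells included several that the compounds lowered in sorted bulk cells. PLSCR2, a phospholipid scramblase gene, stood at 3221 CPM in Endo, CYP26A1, which breaks down retinoic acid, at 858 CPM, the receptor ERBB4 at 176 CPM and the red cell glycoprotein GYPB at 174 CPM. STC1 stood at 254 CPM in Endo against 31.1 in Meso, and COL5A2 at 164 against 6.59. In sorted cells COL5A2 had fallen by 5.57 with BRD and ERBB4 by 1.76 on the log2 scale.

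Meso cells carried further posterior regulators. CDX1 and CDX4, which open the posterior HOX genes, stood at 59.2 and 72.1 CPM. RSPO3, which strengthens Wnt signalling, stood at 54.5 CPM.

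A hypothesis was formed after the clusters were seen, and its test was chosen after that result: the cluster of 238 cells at 36 h led by LHX1, DKK4, APLNR, DKK1, GATA6, FGF17 and CER1 may be cells that respond to Activin A on top of CHIR. Of 49 of its 50 leading genes tested in bulk, 33 rose and 0 fell with Activin A at 24 h, with an adjusted p of 0.00244 under an estimated correlation over 10 comparisons. At 6 h 8 of 45 rose and 1 fell (0.0207). CHIR alone at 6 h also raised 8 of 45 and lowered 0 (0.0879). With JNJ at 24 h 4 of 49 fell and 0 rose (adjusted p = 0.0105 with the preset correlation, and 0.142), and in sorted 72 h cells 6 rose and 27 fell with BRD against Activin A (0.0463). Bulk and single cells come from the same study, and no other cause was tested. The cluster was picked for holding the most primitive streak markers at 36 h. Several of its leading genes had already been seen to rise with Activin A in bulk. The protocol of all 36 h cells lists Activin A and CHIR. The test therefore cannot show that this cluster in particular holds the responding cells.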
